A study of Mus musculus with 9 samples.

How the data were processed

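Bulk RNA-seq was made from primary skin fibroblasts of newborn mice in 3 groups of 3 libraries: control, tumor-conditioned medium (TCM) and TCM treated with a lipid-removing reagent. Per the labels' protocols, the libraries were prepared with a stranded Illumina TruSeq kit from RNA isolated with a Qiagen RNeasy kit. Per the submitters' processing notes, Trim Galore 0.6.6, FastQC, STAR 2.7.9a, DESeq2 and the build mm10 were used. The read counter, its strand setting and the gene annotation are not given in the sources used here. Genes that overlap or share reads with near-identical copies are therefore uncertain, which concerns Serpina3h, and mt-Atp8, which overlaps mt-Atp6.

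The deposited table holds 55401 genes in 9 columns. Its values are the authors' signal of read counts divided by 1 size factor per library. Within a column the values are whole multiples of 1 step: with a tolerance of 0.01, 100% of values came out as whole reads in every library. The factor implied by the step matched a median-of-ratios size factor to within 2e-12, so the scaling is known from the values. Recovered reads ranged from 51015024 to 64965906 per library, and since the size factors lie near 1, a gene at 10 normalized counts rests on about that number of reads. By Ensembl identifier without version, 55141 genes were found in GENCODE M21, the GRCm38 annotation, from which names and coordinates were taken; 54349 were found with the version.

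A gene was tested if it had a normalized count of at least 10 in at least 3 of the 9 libraries, which left 16950. The values were transformed to log2(value + 1), and limma 3.58.1 in R 4.3.3 was fitted with 3 group means on all 9 libraries with a variance trend, leaving 6 residual degrees of freedom. The 3 contrasts were TCM against control, lipid-depleted TCM against TCM, and lipid-depleted TCM against control. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p below 0.05. Single values of Glul were also compared by a two-sided exact permutation test, which cannot go below 0.1 with 3 against 3.

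The 34 gene lists (pathways, fibroblast states, markers of other cell types and signs of RNA quality) were fixed before the data were examined. They were tested with camera at a preset inter-gene correlation of 0.01, with p-values adjusted over lists within a comparison, and again with an estimated correlation and with fry. With an estimated correlation, the calls of the cell cycle, NRF2 and fatty acid oxidation lists in lipid-depleted TCM against TCM held, and no other. At an unadjusted p under 0.05 that test gave 6, 8 and 6 lists in the 3 comparisons. Median, mean and test of a list differed in sign in 12 of the tests, none of them called. Reactome sets from fgsea 1.28.0 with 15 to 200 tested members were searched with camera.

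The named genes followed a rule set together with the gene lists. They are Glul; the 5 genes with the largest rise and the 5 with the largest fall per comparison among called genes with a mean of at least 50 in the higher group, no overlap of libraries and a symbol that is not a provisional one; the 2 called genes per list with the largest change in the list's direction, lists taken in order of camera p until 20 genes were reached; and the 5 largest TCM effects among genes turned back by lipid removal and among genes kept within 0.5. A gene named for 1 comparison may be given in the others, and any other gene named was chosen after its values were seen. No gene was named for a Reactome set. Some genes that the rule takes are not reported here.

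The count of genes turned back by lipid removal was set against simulated unchanged groups and against independent lists. The slope of the lipid-depletion effect on the TCM effect was corrected for the covariance that noise in the shared TCM libraries adds. Folds of genes with 0 reads in a group use a floor of 3 reads over the group, and ratios with 1 to 3 reads carry an exact 95% interval, both for counting error only.

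The code was tested on simulated counts for TCM against control over 16721 genes. limma recovered 26% of genes changed 1.2-fold, 90% of those changed 1.5-fold, 96% at 2-fold and 100% at 4-fold, and called 0.0726% of unchanged genes. Only 50 genes per fold were changed and 16521 were not, whereas 60.5% of genes were called in the data. These rates depend on the share of changed genes, so they do not give the rate of false calls in the data. A simulated slope of -0.5 was estimated at -0.51.

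The alternatives were pseudocounts of 0.5 and 5, no filter or a filter at 50, scaling to the same library total, TMM scaling, quantile normalization, edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on the recovered reads, a robust variance prior, a fit of the compared groups alone, stricter thresholds, the replicate number as a block, and leaving out each library. On the recovered reads the edgeR count test called 10232, 7744 and 10174 genes in the 3 comparisons. No 2 replicates agreed within sampling noise: the chi-square per degree of freedom between replicates was 2.46 to 38.7, highest between TCM replicates 1 and 2.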

Results

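RNA was sequenced from primary fibroblasts grown out of the skin of newborn wild-type mice. The 9 libraries fall into 3 groups of 3: control cultures, cultures given tumor-conditioned medium (TCM), and cultures given TCM from which lipids had been removed. TCM was medium that YUMM1.7 cells, a mouse melanoma line, had conditioned for 24 h. Lipids were removed from it with Cleanascite, a reagent that adsorbs lipids. The deposited values are read counts per gene divided by a size factor per library, called normalized counts below. Whole reads recovered from them ranged from 51015024 to 64965906 per library. The fibroblasts were maintained in DMEM with 10% fetal bovine serum, but the labels do not say which medium the control cultures received during the treatment, nor how long the treatment lasted. They do not say whether the replicates came from separate animals or cultures, so the p-values measure only the spread between these libraries. Fold changes are on the log2(normalized count + 1) scale, which understates the change of genes with few reads. Each value is a mean ± SD of 3 libraries, and adjusted p-values of single genes are from limma with Benjamini-Hochberg adjustment over 16950 genes.

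The title of the study concerns glutamine synthesis in fibroblasts instructed by tumor cells, which makes Glul, the gene of glutamine synthetase, the first gene to compare. Glul (ENSMUSG00000026473.16, chromosome 1, 153899944 to 153909723, plus strand, GRCm38, the assembly also called mm10) was higher in TCM and lay in between in lipid-depleted TCM. Its normalized count was 882 ± 53.3 (SD, n = 3) in control, 1628 ± 120 in TCM and 1170 ± 72.8 in lipid-depleted TCM. TCM raised Glul by 0.88 on the log2 scale (SE 0.07, limma adjusted p = 3.7e-07), which is 1.84-fold. Between TCM and lipid-depleted TCM the log2 change was -0.47 (SE 0.07, limma adjusted p = 0.00018). Against control, Glul was still 0.41 higher on the log2 scale in lipid-depleted TCM (limma adjusted p = 0.00035). In each of these comparisons the libraries of the groups did not overlap, and the two-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 can give.

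**Figure D1:**
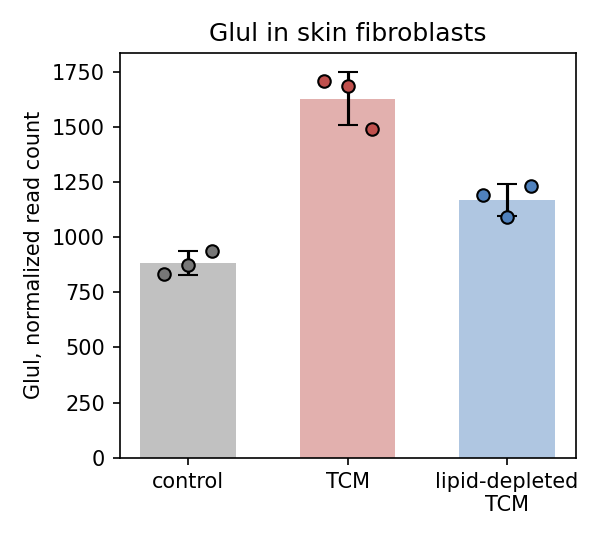
Normalized read count of Glul (vertical axis, from 0) in the 3 groups; bars are means of 3 libraries, error bars are SDs and points are single libraries. The means were 882 in control, 1628 in TCM and 1170 in lipid-depleted TCM, with no overlap between groups.

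The rise of Glul was not shared by the list of glutamine and glutamate genes around it. In TCM against control, 12 of the 32 tested members rose and 12 fell (12 and 13 adjusted over the list alone), and the list was not called by camera (adjusted p = 0.826). The median member was slightly higher (log2 0.02) while the mean was -0.09. From TCM to lipid-depleted TCM, 6 members rose and 9 fell (6 and 10 adjusted over the list alone), again with no call (adjusted p = 0.724), and against control lipid-depleted TCM raised 9 and lowered 13 (10 and 13 adjusted over the list alone; adjusted p = 0.446). The test fry asks whether a list changed at all, not whether it changed more than other genes. It called this list lower against control in TCM (adjusted p = 0.0022) and in lipid-depleted TCM (adjusted p = 0.00056). From TCM to lipid-depleted TCM fry made no call (adjusted p = 0.288).

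TCM against control asks what the melanoma-conditioned medium did to fibroblasts. The cells lost transcripts of the contractile apparatus, the extracellular matrix and sterol synthesis, and gained transcripts of interferon-stimulated genes and secreted inflammatory factors. Myh11, smooth muscle myosin heavy chain, fell from 7966 ± 562 to 407 ± 45.9 normalized counts. Eln, which encodes elastin, fell from 4233 ± 377 to 224 ± 0.886, and Fdps, farnesyl diphosphate synthase of sterol synthesis, fell from 1114 ± 22.2 to 232 ± 68.1. Isg15, an interferon-induced ubiquitin-like protein, rose from 110 ± 77.6 to 928 ± 155, and Il6, the cytokine interleukin 6, rose from 30.9 ± 5.09 to 197 ± 28.6. Of 16950 genes tested, limma called 10248 (4995 higher and 5253 lower), and 2288 of these changed at least 2-fold (892 higher and 1396 lower). The libraries of the groups did not overlap for 63.9% of genes, against 10% by chance. Scaling each library to the same total moved the median of all genes by 0.15 on the log2 scale and made 66.3% of calls higher instead of 48.7%, so the balance of higher and lower calls depends on scaling.

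Contractile genes, matrix genes and TGF-beta targets fell in TCM. In the contractile myofibroblast list 19 of 20 genes fell (camera adjusted p = 9.0e-13; adjusted p = 0.217 with an estimated correlation). Mylk, myosin light chain kinase, fell from 7255 ± 131 to 469 ± 34.4 normalized counts, and Acta2, smooth muscle actin, from 291560 ± 3266 to 60168 ± 5325. In the collagen and matrix list 26 of 32 fell and 3 rose (adjusted p = 7.7e-10; adjusted p = 0.217 with an estimated correlation), and among them Col11a1, a fibrillar collagen chain, fell by 2.44 on the log2 scale. In the TGF-beta target list 19 of 24 fell (adjusted p = 4.8e-08; adjusted p = 0.263 with an estimated correlation). Id2 and Id3, inhibitors of helix-loop-helix transcription factors, changed by -3.21 and -3.03 on the log2 scale. Markers of another cell type moved the same way: 8 of 10 pericyte markers fell and 2 rose (adjusted p = 0.0011; adjusted p = 0.217 with an estimated correlation), Myh11 being in both lists.

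Lipid synthesis, cell cycle and protein folding genes also fell in TCM. In the cholesterol synthesis list 25 of 26 genes fell and 1 rose (adjusted p = 1.6e-14; adjusted p = 0.217 with an estimated correlation). Besides Fdps, Tm7sf2, a sterol reductase, fell by 2.29 on the log2 scale. In the fatty acid synthesis list 17 of 22 fell (adjusted p = 3.4e-05; adjusted p = 0.0881 with an estimated correlation), including Fads2, a fatty acid desaturase, from 7022 ± 146 to 2240 ± 101 normalized counts. In the cell cycle list 27 of 35 fell and 4 rose (adjusted p = 5.8e-07; adjusted p = 0.263 with an estimated correlation). Kif23, a kinesin of cytokinesis, fell by 1.30 and Cdc20, an activator of the anaphase-promoting complex, fell by 1.29. In the list of the unfolded protein response of the endoplasmic reticulum 16 of 22 fell (adjusted p = 0.00053; adjusted p = 0.357 with an estimated correlation). Among these, Calr, the chaperone calreticulin, fell by 1.19 and Pdia6, a disulfide isomerase, fell by 0.96.

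Interferon-stimulated and inflammatory genes rose in TCM. In the interferon list 23 of 28 genes rose and 1 fell (adjusted p = 5.6e-08; adjusted p = 0.408 with an estimated correlation). The one that fell was Cxcl10, with 33.4 ± 35.9 normalized counts in control and 6.97 ± 4.87 in TCM, libraries that overlapped. Oas2, an antiviral oligoadenylate synthetase, rose by 2.99 on the log2 scale from 1.48 ± 1.66 normalized counts. The control libraries spread widely for these genes, as the SD of Isg15 shows. In the list of inflammatory fibroblast factors 16 of 23 rose and 4 fell (adjusted p = 0.0002; adjusted p = 0.263 with an estimated correlation). Ccl11, the chemokine eotaxin, rose from 33.8 ± 3.91 to 307 ± 21.3. In the NRF2 oxidative stress list 16 of 24 rose and 3 fell (adjusted p = 0.00059; adjusted p = 0.104 with an estimated correlation). Transcripts of the mitochondrial genome, used here as a sign of RNA quality, rose with these groups: 13 of 13 were higher (adjusted p = 0.00019; adjusted p = 0.34 with an estimated correlation). Their share of each library was 1.78% to 1.87% in control, 2.69% to 3.16% in TCM and 1.85% to 2.15% in lipid-depleted TCM.

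Adjusted over the list alone, 11 of the 12 called lists had the same counts, and the NRF2 list had 16 higher and 5 lower. With an estimated correlation camera called 0 of the 34 lists, and 6 had an unadjusted p under 0.05. The genes with the largest single changes lie outside these lists. Mcoln2, an endolysosomal cation channel, rose from 4.76 ± 1.55 to 144 ± 25.9 normalized counts, and Grm4, a glutamate receptor, from 8.05 ± 2.63 to 164 ± 24.9. Il13ra2, a decoy receptor of interleukin 13, rose by 4.54 on the log2 scale. Gucy1a1, a subunit of soluble guanylate cyclase, fell from 394 ± 51.4 to 4.14 ± 1.99. Gpr183, an oxysterol receptor, had 58.4 ± 6.24 in control and no read in any TCM library, which makes it at least 61.3-fold lower with a floor of 3 reads over the group. Where a group had 1 to 3 reads, the ratio of reads carries a wide counting interval. Iqcm was 149-fold higher in TCM (95% interval 26.5 to 5937), Dthd1 55.6-fold higher (18.7 to 272) and Tnfsf15, a cytokine of the TNF family, 106-fold lower (35.9 to 518). Serpina3h was 113-fold lower (38.2 to 549), but it belongs to a family of near-identical copies between which reads can be split. These intervals cover counting error only.

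The comparison of lipid-depleted TCM with TCM asks which effects of the medium depend on what the lipid-removing reagent takes out. No group is labelled as control medium treated with the reagent. Removing lipids lowered cell cycle genes, interferon-stimulated genes and mitochondrial transcripts, and raised contractile genes, matrix genes and 20 of 30 NF-kB targets. Mki67, which encodes the proliferation marker Ki-67, fell from 6521 ± 1042 to 2093 ± 272 normalized counts. Isg15 fell from 928 ± 155 to 149 ± 33.2. Cxcl10, a chemokine that attracts T cells, rose from 6.97 ± 4.87 to 744 ± 81.8, and Acta2 rose from 60168 ± 5325 to 127620 ± 1144. limma called 7664 genes (3850 higher and 3814 lower), 1030 of them at least 2-fold (529 higher and 501 lower). The libraries of the groups did not overlap for 52.4% of genes, against 10% by chance.

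With lipids removed, 34 of 35 cell cycle genes fell (adjusted p = 2.9e-27), a call that held with an estimated correlation (adjusted p = 0.0486). Cdc6, a DNA replication licensing factor, fell by 1.82 on the log2 scale. In the interferon list 18 of 28 fell and 2 rose (adjusted p = 0.00023; adjusted p = 0.588 with an estimated correlation). Ifi44 fell from 70.6 ± 8.11 to 6.4 ± 1.67 normalized counts, Rtp4 from 127 ± 18.1 to 17 ± 6.14, and Usp18, which removes ISG15 from proteins, fell by 2.75 on the log2 scale. Zbp1, a sensor of nucleic acids outside the list, fell from 205 ± 18.2 to 24.6 ± 1.62. The mitochondrial transcripts fell with these groups, 11 of 13 genes (12 adjusted over the list alone; adjusted p = 3.9e-06; adjusted p = 0.219 with an estimated correlation), and mt-Nd2 fell by 1.10. In the glycolysis list 15 of 20 fell and 1 rose (15 and 2 adjusted over the list alone; adjusted p = 0.00011; adjusted p = 0.212 with an estimated correlation). Pkm, the glycolytic pyruvate kinase, fell from 52465 ± 2848 to 29867 ± 732, and Slc16a3, a lactate transporter, fell by 0.91. In the NRF2 list 13 of 24 fell (13 with 1 higher adjusted over the list alone; adjusted p = 0.0002), and this call held with an estimated correlation (adjusted p = 0.0486). Nqo1, a quinone reductase, fell by 0.86 and Pgd, an enzyme of the pentose phosphate pathway, fell by 0.76.

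Cholesterol synthesis genes, already low in TCM, were lower again without lipids. In that list 16 of 26 fell and 2 rose (adjusted p = 0.00068; adjusted p = 0.424 with an estimated correlation). Stard4, a sterol carrier, fell from 1064 ± 134 to 724 ± 58.5 normalized counts, and Idi1 from 2811 ± 139 to 2008 ± 283. Genes of fatty acid oxidation and PPAR targets rose, 22 of 33 with 1 lower (23 and 1 adjusted over the list alone; adjusted p = 1.3e-05), a call that held with an estimated correlation (adjusted p = 0.0486). Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose by 1.40 on the log2 scale. The lipid droplet and lysosome list rose weakly, 8 of 24 with 3 lower (9 and 3 adjusted over the list alone; adjusted p = 0.0419; adjusted p = 0.224 with an estimated correlation). That call was lost with edgeR (adjusted p = 0.0587), in a fit of these groups alone (adjusted p = 0.0521), without TCM replicate 2 (adjusted p = 0.0624) and without lipid-depleted TCM replicate 3 (adjusted p = 0.0539). Over 22 alternatives its adjusted p ranged from 0.0124 to 0.0624.

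Contractile genes rose in 16 of 20 cases with none lower (adjusted p = 1.9e-08; adjusted p = 0.224 with an estimated correlation), Myh11 by 1.32 on the log2 scale. Matrix genes rose in 20 of 32 cases with 2 lower (adjusted p = 5.6e-06; adjusted p = 0.224 with an estimated correlation), Col11a1 by 1.99. Pericyte markers rose with them, 7 of 10 (adjusted p = 0.00012; adjusted p = 0.136 with an estimated correlation). Abcc9 rose by 2.95 and Kcnj8 by 2.21, both subunits of an ATP-sensitive potassium channel. In the matrix degradation list 12 of 23 rose and 6 fell (13 and 6 adjusted over the list alone; adjusted p = 0.0309; adjusted p = 0.253 with an estimated correlation). NF-kB targets rose in 20 of 30 cases with 3 lower (adjusted p = 0.00088; adjusted p = 0.135 with an estimated correlation). Their summed normalized count did not rise: it was 65232 to 65694 per library in control, 112480 to 115620 in TCM and 108160 to 110520 in lipid-depleted TCM. Csf1, the most abundant of them, went from 23829 ± 434 to 66360 ± 1515 and 57646 ± 1191 in the same order. Ccl5, a chemokine for T cells and monocytes, rose from 2.23 ± 0.573 to 62 ± 5.55 normalized counts. Outside the named lists, Kank4 and Chodl rose by 3.70 and 3.68 on the log2 scale. The inflammatory fibroblast list split, with 9 of 23 genes higher and 11 lower (10 and 11 adjusted over the list alone) and no call (adjusted p = 0.52). Its mean was 0.16 while its median was -0.25. Il6 fell by 2.32 and Ccl11 fell by 1.07, whereas Cxcl2, a neutrophil chemokine, rose by 3.38 and Saa3, an acute-phase protein, rose from 6.67 ± 4.35 to 129 ± 29.4 normalized counts.

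**Figure D2:**
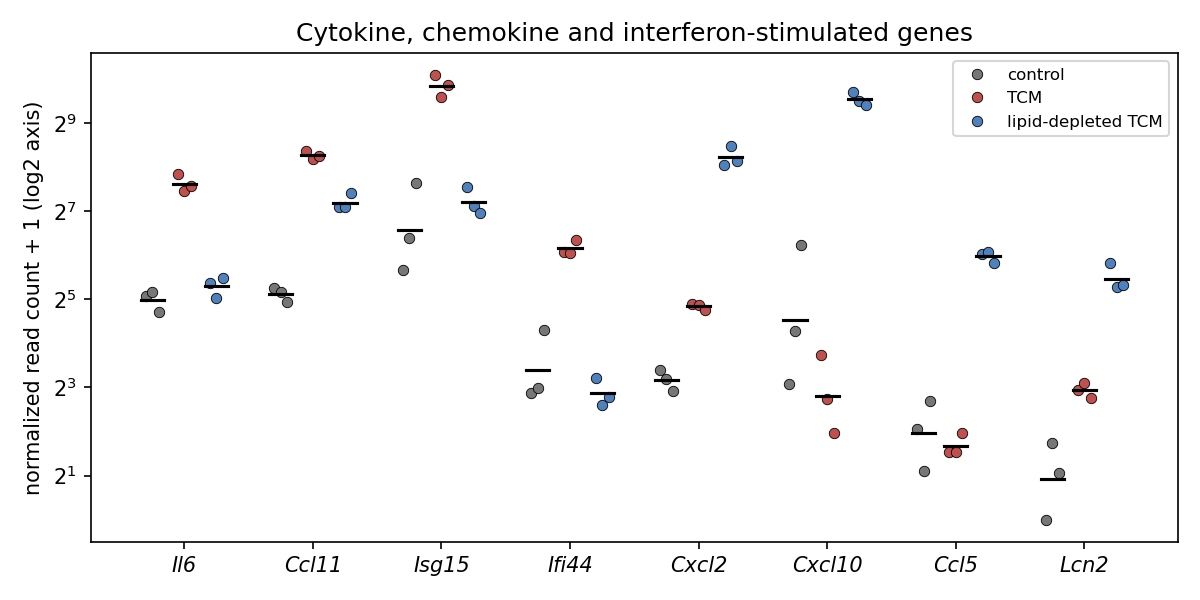
Normalized read count plus 1 (log2 axis) of 8 genes in single libraries (points) of control, TCM and lipid-depleted TCM; horizontal lines are means on the log scale. Il6, Ccl11, Isg15 and Ifi44 are highest in TCM, whereas Cxcl2, Cxcl10, Ccl5 and Lcn2 are highest in lipid-depleted TCM, where Cxcl10 averages 744.

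Lipid-depleted TCM against control shows what the medium did without the lipids that the reagent removed. Contractile, matrix, sterol synthesis and cell cycle genes stayed below control, and NF-kB targets and inflammatory fibroblast factors stood above it. Cxcl2 was at 299 ± 50.7 normalized counts against 8.08 ± 1.5 in control, and Rragd, a GTPase that signals nutrients to mTORC1, at 2546 ± 94.2 against 140 ± 18.3. Plk1, a mitotic kinase, was at 432 ± 15.2 against 2762 ± 171, and Idi1, an isoprenoid isomerase of sterol synthesis, at 2008 ± 283 against 10251 ± 118. limma called 10168 genes (4984 higher and 5184 lower), 2352 of them at least 2-fold (1013 higher and 1339 lower). Libraries did not overlap for 71.2% of genes, against 10% by chance. With libraries scaled to the same total, 65.6% of calls were higher instead of 49.0%.

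In the cell cycle list 33 of 35 genes were lower than in control (adjusted p = 3.7e-20; adjusted p = 0.0862 with an estimated correlation), and Birc5, a mitotic regulator, had a log2 difference of -2.67. Cholesterol synthesis genes were lower in 25 of 26 cases (adjusted p = 3.5e-16; adjusted p = 0.112 with an estimated correlation) and fatty acid synthesis genes in 16 of 22, with 4 higher (17 and 4 adjusted over the list alone; adjusted p = 4.2e-05; adjusted p = 0.0862 with an estimated correlation). Scd2, a stearoyl-CoA desaturase, was at 22773 ± 830 normalized counts against 81558 ± 364. Contractile genes were lower in 19 of 20 cases (adjusted p = 3.2e-10; adjusted p = 0.249 with an estimated correlation), with Cnn1, which encodes calponin, at 2171 ± 124 against 20988 ± 322. TGF-beta targets were lower in 18 of 24 cases (19 adjusted over the list alone; adjusted p = 1.2e-06; adjusted p = 0.249 with an estimated correlation) and matrix genes in 24 of 32 (25 adjusted over the list alone; adjusted p = 3.4e-06; adjusted p = 0.249 with an estimated correlation). Pericyte markers moved with them, 8 of 10 lower and 2 higher (adjusted p = 0.0232; adjusted p = 0.278 with an estimated correlation). Genes of the unfolded protein response were lower in 17 of 22 cases (adjusted p = 4.2e-05; adjusted p = 0.249 with an estimated correlation) and glycolytic genes in 14 of 20, with 4 higher (adjusted p = 0.00966; adjusted p = 0.326 with an estimated correlation).

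NF-kB targets were higher than in control in 20 of 30 cases (adjusted p = 0.00024; adjusted p = 0.0862 with an estimated correlation), inflammatory fibroblast factors in 15 of 23 (adjusted p = 0.0015; adjusted p = 0.278 with an estimated correlation) and interferon-stimulated genes in 16 of 28 (adjusted p = 0.0018; adjusted p = 0.561 with an estimated correlation). Lcn2, an iron-sequestering lipocalin, had 44 ± 9.93 normalized counts against 1.14 ± 1.16, a read ratio of 40.6 with a 95% interval of 13.6 to 199. Fatty acid oxidation genes were higher in 19 of 33 cases with 5 lower (20 and 5 adjusted over the list alone; adjusted p = 0.0017; adjusted p = 0.0862 with an estimated correlation), with Angptl4, an inhibitor of lipoprotein lipase, at 2766 ± 108 against 883 ± 27.4. Factors that act on macrophages were higher in 14 of 23 cases with 6 lower (15 and 6 adjusted over the list alone; adjusted p = 0.0122; adjusted p = 0.202 with an estimated correlation). Lipid droplet and lysosome genes were higher in 15 of 24 (15 with 4 lower adjusted over the list alone; adjusted p = 0.0301; adjusted p = 0.249 with an estimated correlation). Skeletal muscle markers, a sign of other cells, were higher in 9 of 13 cases (adjusted p = 0.0357; adjusted p = 0.51 with an estimated correlation). With libraries scaled to the same total, the calls of the macrophage list (adjusted p = 0.0602), the lipid droplet list (adjusted p = 0.0639) and the muscle markers (adjusted p = 0.0786) were lost. The muscle call was also lost with quantile normalization (adjusted p = 0.0964), edgeR (adjusted p = 0.144), DESeq2 (adjusted p = 0.178), a fit of these groups alone (adjusted p = 0.0504), without control replicate 3 (adjusted p = 0.077) and without lipid-depleted TCM replicate 3 (adjusted p = 0.0658). Over 22 alternatives the adjusted p ranged from 0.0001 to 0.0602 for the macrophage list, from 0.0067 to 0.0639 for the lipid droplet list and from 0.0076 to 0.178 for the muscle markers.

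Among the lowest genes against control, Pcp4l1 had 16.5 ± 8.25 normalized counts against 1215 ± 11.2 and Kcnk3, a potassium channel, 4.22 ± 2.92 against 232 ± 19.1. Grin3a, an NMDA receptor subunit, had 3.54 ± 4.54 against 154 ± 9.42. Fam196b and Prss46 had 3 reads each over the lipid-depleted libraries, which gives read ratios of 111 (95% interval 37.6 to 541) and 86.4 (29.2 to 422). Ppef1 was 4.05 higher on the log2 scale.

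The last comparison sets the effect of lipid removal against the effect of TCM, gene by gene. Of the genes called in TCM against control, 3908 (38.1%) were called with the opposite sign when lipids were removed: 1826 raised by TCM and then lowered, and 2082 lowered by TCM and then raised. Independent lists of the same sizes would share 1124 and 1193 genes, and 20 simulations of unchanged groups shared at most 0, a count that tells little, since unchanged groups leave few genes to call. The largest TCM effects among genes turned back were those of Gucy1a1, Gper1, Tnfsf15, Serpina3h and Gjb2. The return of Gper1 (1.58 ± 2.74 normalized counts in TCM and 5.69 ± 1.39 in lipid-depleted TCM) and of Tnfsf15 rested on few reads, with libraries that overlapped. Tnfsf15 had 3 reads in TCM and 15 in lipid-depleted TCM, a ratio of 4.89 with a 95% interval of 1.38 to 26.3. Gjb2, which encodes the gap junction protein connexin 26, went from 3148 ± 193 normalized counts in control to 56.6 ± 13 in TCM and 246 ± 11.9 in lipid-depleted TCM. With libraries scaled to the same total, 38.5% instead of 53.3% of the genes turned back were ones that TCM had lowered.

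Another 664 genes raised by TCM were raised further without lipids, and 907 lowered genes were lowered further, against 1135 and 1182 in independent lists. Both media raised 3418 genes and lowered 3763 against control, against 1469 and 1607 in independent lists. For 4400 genes changed the same way by both media, the 95% interval of the difference between the media lay within 0.5 on the log2 scale. The largest of these were Wif1, a secreted Wnt inhibitor, lowered from 618 ± 17.7 normalized counts to 36.5 ± 4.48 in TCM and 39.3 ± 2.92 in lipid-depleted TCM, and Chchd10, a mitochondrial protein, raised from 127 ± 8.95 to 2126 ± 712 and 2066 ± 150. Tenm4 and Cxadr, both cell surface proteins, were raised by 3.47 and 3.14 on the log2 scale in TCM, and Kctd12 fell by 3.32.

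Across genes, which are not independent replicates, the lipid-depletion effect had a slope of -0.22 on the TCM effect after removal of the noise that shared TCM libraries add, where -1 would be a full return to control. The jackknife SE was 0.0346 and 77.8% of the TCM effect remained. With genes chosen on other libraries, the slope was -0.22 to -0.21. The correlation of the effects was -0.37 (-0.50 in simulated unchanged groups), and the covariance was -0.16 against a simulated -0.0204. For the effects of the 2 media against control, the correlation was 0.785 (0.501 simulated) and the covariance 0.509 (0.0204 simulated). The 3 libraries of a group cannot be split into parts of at least 2 libraries each, so part of the excess of the shared counts may come from the shared libraries.

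**Figure D3:**
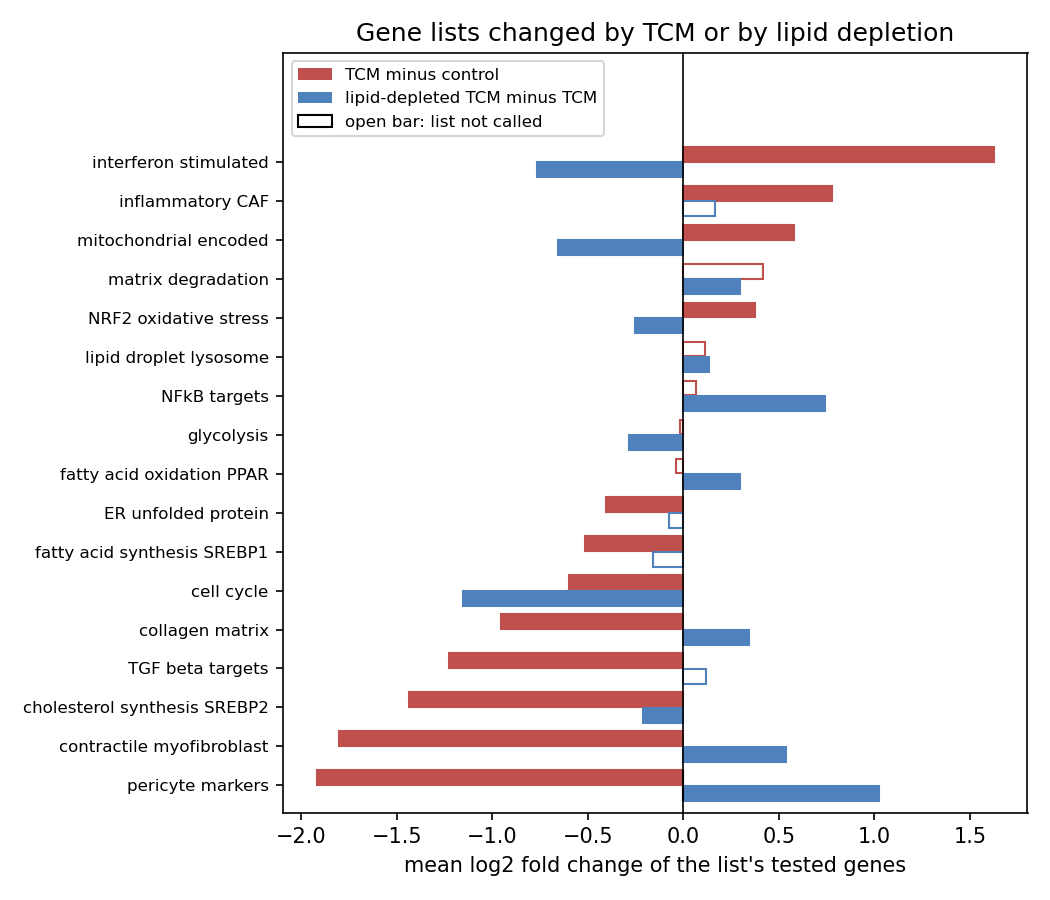
Mean log2 fold change (horizontal axis) over the tested genes of each gene list called in TCM against control or in lipid-depleted TCM against TCM; red bars are TCM minus control, blue bars lipid-depleted TCM minus TCM, and open bars are lists that camera did not call. Contractile genes averaged -1.80 in TCM and 0.54 on lipid removal, whereas cell cycle genes averaged -0.60 and -1.15.

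Of the 34 lists, 15 were called in no comparison (lowest adjusted p = 0.0521). In TCM against control their counts of higher and lower genes were 8 and 4 of 21 for TLR4 and lipid sensing, 4 and 4 of 13 for LXR targets, 10 and 5 of 23 for hypoxia, 14 and 9 of 32 for the ATF4 stress response, 8 and 6 of 17 for p53 targets, 14 and 7 of 25 for immediate-early genes and 9 and 11 of 26 for growth factors. Markers of other cells gave 4 and 2 of 9 for melanocytes and melanoma, 0 and 1 of 9 for keratinocytes, 2 and 4 of 6 for leukocytes, 2 and 4 of 9 for endothelium, 2 and 4 of 9 for adipocytes and 2 and 2 of 11 for Schwann cells. In summed normalized counts the melanocyte and melanoma markers were at 5376 to 5480 per library in control, 15106 to 17896 in TCM and 17826 to 18597 in lipid-depleted TCM, mostly from Gpnmb (3868 ± 178, 12778 ± 1535 and 15111 ± 378), while Pmel fell in TCM and Tyrp1, Dct and Mlana were not called there. Mlana rose from 3.51 ± 2.95 in TCM to 32.2 ± 4.61 in lipid-depleted TCM. The adipocyte markers were at 11134 to 11424, 26739 to 28416 and 34415 to 35843, mostly from Lpl (9163 ± 182, 25657 ± 742 and 33623 ± 684), while Adipoq fell in TCM. Replication histones, a sign of RNA selection, gave 1 and 6 of 11. The lists of NF-kB targets (8 and 10 of 30), fatty acid oxidation (10 and 9 of 33), glycolysis (5 and 9 of 20), matrix degradation (12 and 8 of 23), lipid droplets (13 and 6 of 24), macrophage-acting factors (10 and 7 of 23) and skeletal muscle (7 and 1 of 13) were not called in that comparison either. Adjusted over the list alone, these counts were 14 and 10 for ATF4, 2 and 5 for adipocytes, 10 and 8 for fatty acid oxidation, 13 and 7 for lipid droplets and 11 and 7 for macrophage-acting factors, and the same for the others.

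Some lists that were not called gained a call under an alternative. In TCM against control, edgeR and DESeq2 called macrophage-acting factors (adjusted p = 0.0119 and 0.00366) and hypoxia genes (adjusted p = 0.000938 and 0.000677) higher. In lipid-depleted TCM against control, they called matrix degradation higher (adjusted p = 0.00627 and 0.00191). With limma-voom on the same reads all 102 list tests kept their outcome. Some lists also gained a call when 1 library was left out. The immediate-early list did so in TCM against control without TCM replicate 1 (adjusted p = 0.0286). From TCM to lipid-depleted TCM, it was called without TCM replicate 1 (adjusted p = 0.00572), TCM replicate 2 (adjusted p = 0.0426) and lipid-depleted TCM replicate 3 (adjusted p = 0.0329). In the same comparison the fatty acid synthesis list was called without TCM replicate 2 (adjusted p = 0.0314) and lipid-depleted TCM replicate 2 (adjusted p = 0.0365), hypoxia genes without lipid-depleted TCM replicate 2 (adjusted p = 0.046) and replicate 3 (adjusted p = 0.0481), and TGF-beta targets without TCM replicate 3 (adjusted p = 0.0494). Melanocyte and melanoma markers, a sign of other cells, were higher in 4 of 9 cases in lipid-depleted TCM against control (adjusted p = 0.0549). They were called without control replicate 1 (adjusted p = 0.0412) or 3 (adjusted p = 0.0411) and without lipid-depleted TCM replicate 1 (adjusted p = 0.032) or 2 (adjusted p = 0.0435). Over 22 alternatives the adjusted p ranged from 0.0243 to 0.31 for the immediate-early list in TCM against control. From TCM to lipid-depleted TCM it ranged from 0.00572 to 0.171 for that list, from 0.0016 to 0.0786 for fatty acid synthesis, from 0.0101 to 0.09 for hypoxia and from 0.00664 to 0.39 for TGF-beta targets, and for the melanocyte markers against control from 0.00745 to 0.127.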

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

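The tests of explanations and the splits of libraries in this part were chosen after the results were seen. For 6 named genes, TCM and lipid-depleted TCM moved in opposite directions against control, with each change called and with a called difference between the media, the test of that difference. The log2 difference of lipid-depleted TCM minus TCM was 6.72 for Cxcl10, 4.28 for Saa3, 3.68 for Chodl, 1.40 for Pdk4, -0.76 for Pgd and -1.09 for mt-Atp8. Cxcl10 had 33.4 ± 35.9 normalized counts in control and 6.97 ± 4.87 in TCM, so its libraries overlapped there although limma called the fall (log2 -1.72, adjusted p = 0.03). Over all tested genes, 494 showed such opposite directions, and 0 of the 34 lists did.

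The first pattern weighed is the rise of NF-kB targets with lipid removal, in 20 of 30 tested genes with a median log2 change of 0.29 over the 30 (0.63 over the 20), which leukocytes in the cultures could bring. The summed normalized count of 18 leukocyte markers with a TCM mean under 100 was 162 ± 21.8 in TCM and 126 ± 23.8 in lipid-depleted TCM, a change of -36.0 (SE 18.6). This fall stayed within 2 standard errors, and other forms of the test were tried: the median of 6 tested markers was -0.08 (SD 0.995), and a sum of 19 markers that included Cd74, the most abundant of them in TCM (505 ± 10.1 there and 213 ± 36.6 in lipid-depleted TCM), changed by -328 (SE 10.3). Lyz2, an abundant macrophage transcript above that limit and so outside the sum of 18, went the other way, from 127 ± 12 in TCM to 365 ± 18.7 in lipid-depleted TCM (control 204 ± 30.8), so leukocytes stay open. The lipid-removing reagent itself rather than the loss of lipids cannot be told apart from lipid removal, because 0 libraries are labelled as control medium treated with the reagent. The response to the medium without its lipids stays an untested biological explanation.

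The second pattern is that cholesterol synthesis genes fell in TCM and did not rise when lipids were removed. With libraries scaled to the same total the 26 genes averaged -1.28 (SE 0.109) against a median of 0.15 for all genes. Such scaling moves all genes by nearly the same amount, so this gap was fixed in advance and does not test scaling. It shows only that these genes fell relative to the median gene. If lipids of the medium held these genes down and the reagent removed those lipids, the genes would rise. They averaged -0.21 (SE 0.0431 over genes taken as independent) from TCM to lipid-depleted TCM, with 2 of 26 higher and 16 lower. This value defined the pattern, so it is no separate test. The rise that both conditions together would give was thus not seen, but another effect of the treatment could have masked it. Lipids that the reagent did not remove stay open too. fry, which allows for genes that move together, called the list lower (adjusted p = 0.0034), and camera with an estimated correlation did not (adjusted p = 0.424). The tests differ: fry asks whether the list changed at all, camera whether it changed more than other genes. A candidate explanation that stays open, and was not tested, is a factor of TCM that the reagent leaves in place.

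The third pattern is the loss of pericyte markers in TCM and their partial return. A smaller share of 1 uniform kind of pericyte, with no change within cells, would give back the same fraction of each marker. Among the 8 lowered markers the fraction regained ranged from 8.07% (SE 0.641) for Myh11 to 47.0% (SE 3.28) for Abcc9. The difference of 38.9 percentage points (SE 3.34) argues against a change in the share of 1 uniform cell type alone. Several cell types whose shares change separately could give unequal fractions, and the spread does not test that. Myh11 is also in the contractile list. Scaling to the same total left the 10 markers at a mean of -1.76 (SE 0.673) in TCM against control. This was no test of scaling either, because such scaling moves the markers and the median of all genes nearly alike. A change of these genes within cells, as a response to the medium, may account for the pattern and remains a hypothesis.

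In other splits of the 6 libraries of each comparison limma called at most 0 genes, against 10248 for TCM against control, 7664 for lipid-depleted TCM against TCM and 10168 for lipid-depleted TCM against control; in each, 1 of 10 splits reached the real count. At an unadjusted p under 0.05, limma gave at most 636, 1175 and 169 genes in other splits of the 3 comparisons, and edgeR, run on the same splits, called at most 0, 0 and 0 (652, 1165 and 175 at an unadjusted p under 0.05). With 10 splits a share under 0.05 cannot be reached. Mixing groups that differ this much also puts their difference into the spread, which leaves few genes to call. The low counts therefore show only that the groups differ. For the number of lists called, 4 of 10 splits gave at least the real 12 in the first comparison (highest other 13), 2 of 10 gave at least 13 in the second (highest other 13) and 1 of 10 gave at least 16 in the third (highest other 14), again too few splits for a share under 0.05. Splits that mix the groups thus called as many lists as the real one in 2 comparisons, where the number called does not set the real grouping apart. These calls used camera at the preset inter-gene correlation of 0.01. The estimated correlation ranged from -0.056 for endothelial markers to 0.60 for the interferon list. With it, 0 of the 12, 3 of the 13 and 0 of the 16 real calls held. P-values at the preset value are therefore to be read together with those at the estimated one. Whether the preset value caused the calls in mixed splits was not tested. For the genes turned back, 2 of 100 drawn groupings of the 9 libraries gave at least the real 3908, and all but these gave 0. Groups that mix such different libraries leave almost no gene to call, so the draws show that the groups differ and do not test whether the turning back exceeds chance. The other draw above 0, with 5487, put the 3 control libraries together in the middle role, with TCM and lipid-depleted TCM libraries mixed in the others, and so reflects the structure of the samples.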

How the results depend on the processing

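The direction and call of Glul in all 3 comparisons were the same under each alternative run. So were those of each gene named by the rule, in the comparison that named it, where it passed the filter. Their calls in comparisons that did not name them were not run under the alternatives. The counts stayed within 1.5 times, except under the 2-fold threshold. Requiring an absolute log2 fold change of at least 1 left 2288 genes for TCM against control, 1030 for lipid-depleted TCM against TCM, 2352 for lipid-depleted TCM against control and 432 turned back, because that threshold removes small changes by construction. Without single libraries, the counts ranged from 9201 to 10701, from 6229 to 8615, from 9088 to 11088 and from 3207 to 4594, and the slope from -0.25 to -0.20. Over lists and settings, 2301 tests gave the same outcome as the main one, 88 gained a call, 51 lost one and 2 turned: fry called the adipocyte markers higher although their mean log2 fold change was -0.60 in TCM and -0.50 in lipid-depleted TCM against control. Of the 88 gained calls, 41 came with fry, which asks whether a list changed at all. Of the 51 lost calls, 38 were lost with an estimated correlation, and the cause of the others was not tested. None of the lists called by camera changed direction under the scaling alternatives run. Replicates of different groups share numbers, but libraries with the same number correlated by -0.025 to 0.0274 in their deviations from the group means. Libraries with different numbers correlated by -0.0701 to 0.0842, so the check gave no sign of pairing. It cannot exclude that libraries with the same number share a source. With the replicate number as a block, 9972, 7328 and 9961 genes were called, 3688 were turned back, the slope was -0.22 and Glul changed by 0.88, -0.47 and 0.41. The block also added calls of the immediate-early list from TCM to lipid-depleted TCM (adjusted p = 0.0168) and of the melanocyte markers in lipid-depleted TCM against control (adjusted p = 0.049). Depth limits genes with few reads, such as those with 1 to 3 reads in a group.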

Other observations

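The genes in this paragraph were chosen after their values were seen, from the fixed list of factors that act on macrophages. Spp1, which encodes osteopontin, rose from 2220 ± 51.1 normalized counts in control to 35843 ± 2233 in TCM and stood at 6455 ± 271 in lipid-depleted TCM. Csf1, the macrophage growth factor, rose from 23829 ± 434 to 66360 ± 1515 and stayed at 57646 ± 1191. Ccl2, a monocyte chemokine, was at 1968 ± 86.5, 3390 ± 541 and 7759 ± 415 in the same order. Cxcl12, a chemokine of stromal cells, was at 891 ± 33.4, 2158 ± 87.7 and 4268 ± 158, and Gas6, a ligand of TAM receptors, at 61837 ± 1644, 26529 ± 1154 and 73956 ± 428.

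As a percent of the mean TCM change, lipid removal took back 113% for mitochondrial transcripts, 67.5% for NRF2 genes, 53.4% for pericyte markers, 47.1% for interferon-stimulated genes, 35.8% for matrix genes and 29.7% for contractile genes. It took back 9.72% for TGF-beta targets, from a mean log2 change of 0.12 on lipid removal that was 0.19 without TCM replicate 3. The same measure was -14.6% for cholesterol synthesis genes, -18.3% for genes of the unfolded protein response, -30.9% for fatty acid synthesis genes and -192% for cell cycle genes, where a negative value is a move further from control. For inflammatory fibroblast factors it was -21.0% by the mean, but their median log2 change on lipid removal was -0.25 and fry called them lower (adjusted p = 0.0491), which is a move towards control. These are the 12 lists called in TCM against control, and the change from TCM to lipid-depleted TCM was not called for TGF-beta targets, the unfolded protein response, inflammatory fibroblast factors and fatty acid synthesis. These percentages were not tested against each other. Both changes of a list share the TCM libraries, so noise in those libraries can inflate the share taken back. Unlike the slope, the percentages were not corrected for this and carry no SE. The mitochondrial transcripts were listed as a sign of RNA quality.

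Of 663 Reactome sets, camera called 124 in TCM against control, 156 in lipid-depleted TCM against TCM and 178 in lipid-depleted TCM against control, and 0 in each with an estimated correlation, where 110, 124 and 122 had an unadjusted p under 0.05. In TCM against control, 60 of 93 genes of translation elongation were higher and 6 lower (camera adjusted p = 1.0e-06; adjusted p = 0.111 with an estimated correlation). From TCM to lipid-depleted TCM, 80 of 99 genes of mitotic prometaphase (adjusted p = 2.1e-23; adjusted p = 0.173 with an estimated correlation) and 29 of 32 genes of DNA strand elongation (adjusted p = 6.9e-17; adjusted p = 0.141 with an estimated correlation) were lower.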
